A study of Mus musculus with 9 samples.

How the data were processed

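Total RNA from mouse spleen was hybridised to one-colour arrays with the Cy5 dye, 1 array per mouse, in 3 groups of 3 mice (control, model, Codonopsis), per the labels' protocols. The deposited scanner files hold the processed red intensity of each spot, which the software Agilent Feature Extraction had already background-subtracted, per the file headers. The headers give its version as 11.5.1.1 and the submitters' processing notes as 10.7. The deposited files carry other columns used here only as flags (saturation, outliers, well above background). The deposited matrix of the whole series holds log2 values that the authors had quantile normalized, as judged from equal medians of 6.31 in all 9 columns and correlations of 0.994 or more with the scanner values; its normalization is not given in the sources used here.

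From the scanner files, control spots (4974) and outlier spots were left out, the 175906 other spots were averaged over the 1 or 2 spots of a probe, and log2 of the processed signal was taken minus the 75th percentile of the array. The percentile was taken over the 29420 probes well above background on all 9 arrays, since only 1 of the 9 arrays had a majority of its probes well above background. A probe was tested if it was well above background on all arrays of at least 1 group, and a gene symbol with several probes was represented by the brightest one. This left 42056 features. Of 15 symbols with several testable probes, 7 had probes with opposite signs in at least 1 comparison. Where a probe was not well above background on every array of a group, "at least N-fold" sets the bright group's mean against, per array, the higher of the lowest signal well above background and the probe's own signal.

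The files give no gene names for the 39027 probes of the Agilent catalogue, so messenger RNAs are reported by probe ID. Of 12146 probes for RefSeq model noncoding transcripts 3816 were matched to a symbol through a RefSeq table of the mouse assembly GRCm38, and of 873 for curated noncoding transcripts 842; 27 more carried a literature name. The other classes, such as 28773 NONCODE and 15675 RIKEN clone probes, have no names here. Genes called were therefore counted over catalogue probes and noncoding transcripts over all other probes. Of 579 genes in 31 lists of spleen cell types and pathways fixed before the data were examined, 2 had a named probe and no list reached the 80% needed, so those list tests, the cell type markers and the check of named aging and antioxidant genes are void. In their place, 6 lists of noncoding genes were fixed after the array's names had been read and before any groups were compared: host genes of small nucleolar RNAs, noncoding RNAs linked to p53 or DNA damage, immune noncoding RNAs, opposite-strand transcripts, transcribed pseudogenes, and noncoding transcripts of coding genes. Membership rests on symbols and on biotypes of that table, and neighbouring genes come from it too. The immune list was drawn from general knowledge, and the place of Celrr in it is uncertain. The sources used here do not link Lincred2 to p53 or DNA damage, so its place in that list is uncertain too. The symbol of a coding gene, such as Scnn1b, Smim10l1, Zfp672 or Aopep, stands here for a probe named after a noncoding transcript of that gene. Whether such a probe also binds the messenger RNA was not checked.

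The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, 1 mean per group, two-sided, 6 residual degrees of freedom), with Benjamini-Hochberg adjustment over all 42056 features and a threshold of 0.05. Lists were tested with camera at the preset correlation, with an estimated correlation and with fry. Named genes were chosen by a rule written before the data were examined: up to 8 higher and 8 lower genes per comparison with the largest differences among those past the threshold, filled by the smallest unadjusted p among those at least 2-fold apart, 2 members of each list, and up to 3 noncoding transcripts per direction, of which at most 2 unnamed IDs per direction are printed; predicted genes (Gm names) and RIKEN clone names were left out of the first part. Gm34752 was followed into the other comparisons, and the array values of H2-Q5 were singled out, after their values were seen.

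The labels share replicate numbers across groups. The fit was tested on simulated data with the spread of each feature, with 200 features changed among 42056. In model against control limma recovered 52% of the changes of 2 log2 units and 4% of those of 1. The shares were 51% and 2% in Codonopsis against model, and 54% and 3% in Codonopsis against control. False calls were 8, 3 and 3 in that order. The simulated noise was independent between features and held no slide effect, so these values do not give the recovery in the real arrays. Alternatives covered the background correction (normexp with offset 50 on the median signal, since the files hold no mean signal), the normalization, the deposited matrix, the filter on dim probes, 1 feature per probe, fits to 2 groups, the replicate number, the labelled sex or the slide as a block, trend and robust eBayes, array weights, a rule of 2-fold with an unadjusted p, and leaving out each array. All arrays were scanned on 1 day and each slide in its own scan, so scan and slide are the same batch. P-values measure the spread between mice of these groups, with the slides unevenly spread over them.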

Results

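Spleen RNA from 9 mice was measured on one-colour arrays that carry probes for messenger RNAs and long noncoding RNAs. The mice fell into 3 groups of 3: untreated control mice, model mice given D-galactose with sodium nitrite (labelled 42 days), and mice of the high-dose Codonopsis pilosula group (15 g per kg, labelled 30 days). Control replicate 1 and Codonopsis replicates 1 and 2 were labelled male. The other mice, all model mice among them, were labelled female, so the labelled sex was unevenly spread over the groups. D-galactose with sodium nitrite is a chemical treatment used to mimic aging in mice, and Codonopsis pilosula is a root used in Chinese medicine. Each array carried 97836 probes, of which 34.6% to 51.0% were well above background on an array and 51 had no value on at least 1 array. Control arrays had 46.8%, 44.1% and 51.0% of probes well above background, model arrays 38.5%, 45.8% and 47.6%, and Codonopsis arrays 34.6%, 35.2% and 40.9%. No spot was saturated, and the number of arrays limits the precision of every value below. Levels are log2 signals relative to the 75th percentile of the same array, with SD over n = 3 arrays.

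The arrays lay on 3 slides, and the slides did not cross the groups evenly. Slide 1 held the 3 Codonopsis arrays and model replicate 1, slide 2 held model replicates 2 and 3 with control replicates 1 and 2, and slide 3 held control replicate 3. The first principal component over 29420 probes detected on all arrays carried 57.7% of the variance and placed the 4 arrays of slide 1 on one side and the other 5 arrays on the other. Model replicate 1 correlated with the Codonopsis arrays at a mean r of 0.963 and with the other model arrays at 0.887, across probes, which are not independent replicates. Pairs of arrays on the same slide differed by a mean of 0.50 (root mean square, log2) whether they shared a group or not. Pairs on different slides differed by 0.71 within a group and by 0.80 between groups.

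**Figure D1:**
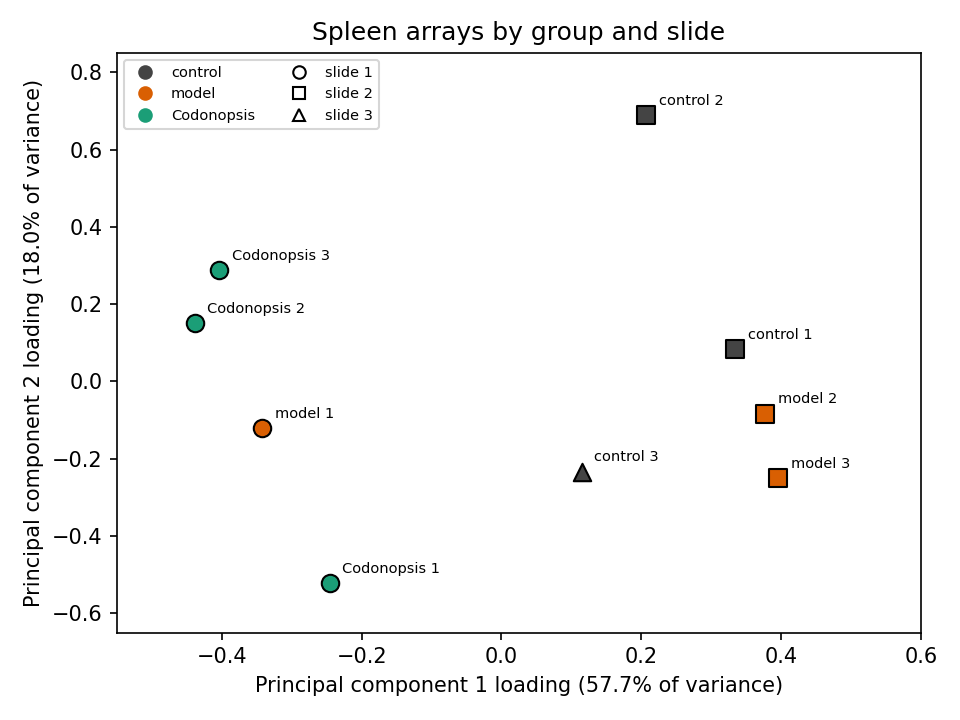
Loadings of the 9 spleen arrays on the first and second principal components of log2 signal, with 57.7% and 18.01% of the variance; colours are groups and symbols are slides. Model replicate 1 sits with the 3 Codonopsis arrays of its slide, and the other model arrays sit near the control arrays.

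The first comparison, model against control, asked which spleen transcripts differ after the D-galactose and sodium nitrite treatment. Gm34752, a noncoding gene next to the olfactory receptor gene Olfr455, was at -2.11 ± 0.37 in model and -0.04 ± 0.28 in control spleens, a log2 difference of -2.07 (SE 0.32). Gm34031, which overlaps the potassium channel subunit gene Kcnmb2, was at -1.84 ± 0.19 in model and -0.57 ± 0.28 in control (difference -1.27, SE 0.24). In the other direction, the unnamed transcript NONMMUT059095 was at -2.41 ± 0.23 in model and -3.48 ± 0.03 in control (difference 1.07, SE 0.20). The model and control arrays did not overlap for any of these 3 transcripts, as chance gives for 10% of transcripts with 3 arrays against 3.

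None of the 22702 catalogue probes and none of the 19354 noncoding transcripts tested passed the threshold in this comparison. The adjusted p of every transcript named here was 0.9998 (limma with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05, limma counted 531 catalogue probes and 623 noncoding transcripts, or 2.34% and 3.22% of those tested (5.85% and 5.20% with slide as a block). With slide as a block, which here amounts to model replicates 2 and 3 against control replicates 1 and 2 on slide 2, the differences were -2.14 for Gm34752, -1.26 for Gm34031 and 0.93 for NONMMUT059095, and no transcript passed. A fit to slide 2 alone called 74 catalogue probes and 29 noncoding transcripts, 97 of the 103 lower in the model, and Gm34752 was among them (adjusted p = 0.0236 with limma). Of those 97, 78 belonged to a set of 84 probes, given with the check of labelled sex. That set was off on both of these model arrays, on for all control arrays and divided within the model and Codonopsis groups. It was picked for such a gap on these same arrays, so its probes are lower in the model here by selection.

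Among the named genes of this comparison, the pseudogene Pisd-ps3 was at -0.49 ± 0.31 in model and -1.49 ± 0.59 in control, and the pseudogene Olfr856-ps1, well above background on 2 of the 3 model arrays, at -2.43 ± 1.39 and -1.35 ± 0.20. H2-Q5, of the class I region of the major histocompatibility complex, averaged 0.14 ± 0.64 in model and -2.49 ± 3.39 in control; control replicate 3 alone read -6.37, not well above background, and the other 8 arrays lay between -1.01 and 0.67. Of 6 host genes of small nucleolar RNAs, 3 were higher and 3 lower in the model, led by Snhg16 with a difference of 0.83 (SE 0.29). Of 5 long noncoding RNAs listed as linked to p53 or DNA damage, 3 were higher and 2 lower. The place of Lincred2 in that list is uncertain. Lncpint, which p53 induces, differed by 0.37 (SE 0.24) and Lincred2 by -0.31 (SE 0.20). In the list of 3 immune noncoding RNAs, in which the place of Celrr is uncertain, AW112010 differed by 0.56 (SE 0.45), Celrr by 0.59 (SE 0.46) and Morrbid, which controls the lifespan of short-lived myeloid cells, by -0.04 (SE 0.39). Opposite-strand transcripts had 4 of 16 higher, with Plxna4os1 at a difference of 0.29 and Wt1os, well above background on 2 of the 3 model arrays, at -0.76. Noncoding transcripts of coding genes had 7 of 20 higher, with that of Aopep at 0.38. That of Zfp672 was not well above background in any model array and was at least 1.87-fold higher in control. Transcribed pseudogenes had 20 of 57 higher. The slide block gave differences of 1.03 for Pisd-ps3, -0.16 for Olfr856-ps1, 1.05 for H2-Q5, 0.79 for Snhg16, 0.40 for Lncpint, -0.14 for Lincred2, 0.48 for AW112010, 0.25 for Celrr, 0.25 for Plxna4os1, -0.13 for Wt1os and 0.27 for Aopep. The median of the opposite-strand list turned from -0.19 to 0.10, that of the pseudogenes from -0.12 to 0.11 and that of the transcripts of coding genes from -0.12 to 0.054. No member passed and no list was called by camera (smallest adjusted p = 0.277).

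The second comparison, Codonopsis against model, asked which transcripts differ between the mice given the plant and the aging model. In all, 2 features fell, and both lay well apart from the model on every array. The noncoding transcript NONMMUT056560 was at -0.04 ± 0.80 in model spleens and was not well above background on any Codonopsis array (-5.37 ± 0.56), which makes it at least 22.2-fold lower with Codonopsis (adjusted p = 0.0330, limma with Benjamini-Hochberg adjustment). The catalogue probe A_55_P2116973, for which the files give no gene, was at -1.02 ± 0.08 in model and -3.42 ± 0.22 in Codonopsis spleens, a difference of -2.40 (SE 0.21, adjusted p = 0.0330 with limma). It was well above background on 1 of the 3 Codonopsis arrays. In control spleens NONMMUT056560 averaged -0.71 ± 0.81, close to the model.

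On slide 1 alone, the 3 Codonopsis arrays against model replicate 1, NONMMUT056560 was at least 11.7-fold higher in the model array and A_55_P2116973 differed by -2.38. With slide as a block the adjusted p was 0.0963 and 0.335 (limma), so neither call held. Both calls were also lost under normexp, quantile normalization, the deposited matrix, the replicate number or labelled sex as a block, and the fit to 2 groups. Both calls also ended when any 1 of the 3 Codonopsis arrays, of model replicates 2 and 3 or of control replicate 2 was left out (limma adjusted p between 0.123 and 0.338). The difference of A_55_P2116973 was -2.52 to -2.32 leaving out 1 array and -2.52 to -1.90 over all alternatives. Its Codonopsis signals lay mostly near background, so these ranges do not show how stable its size is. Without model replicate 1 limma called 6009 catalogue probes (2210 higher, 3799 lower) and 6775 noncoding transcripts (1477 higher, 5298 lower); what remained was Codonopsis on slide 1 against model on slide 2, so slide and group could not be told apart there.

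**Figure D2:**
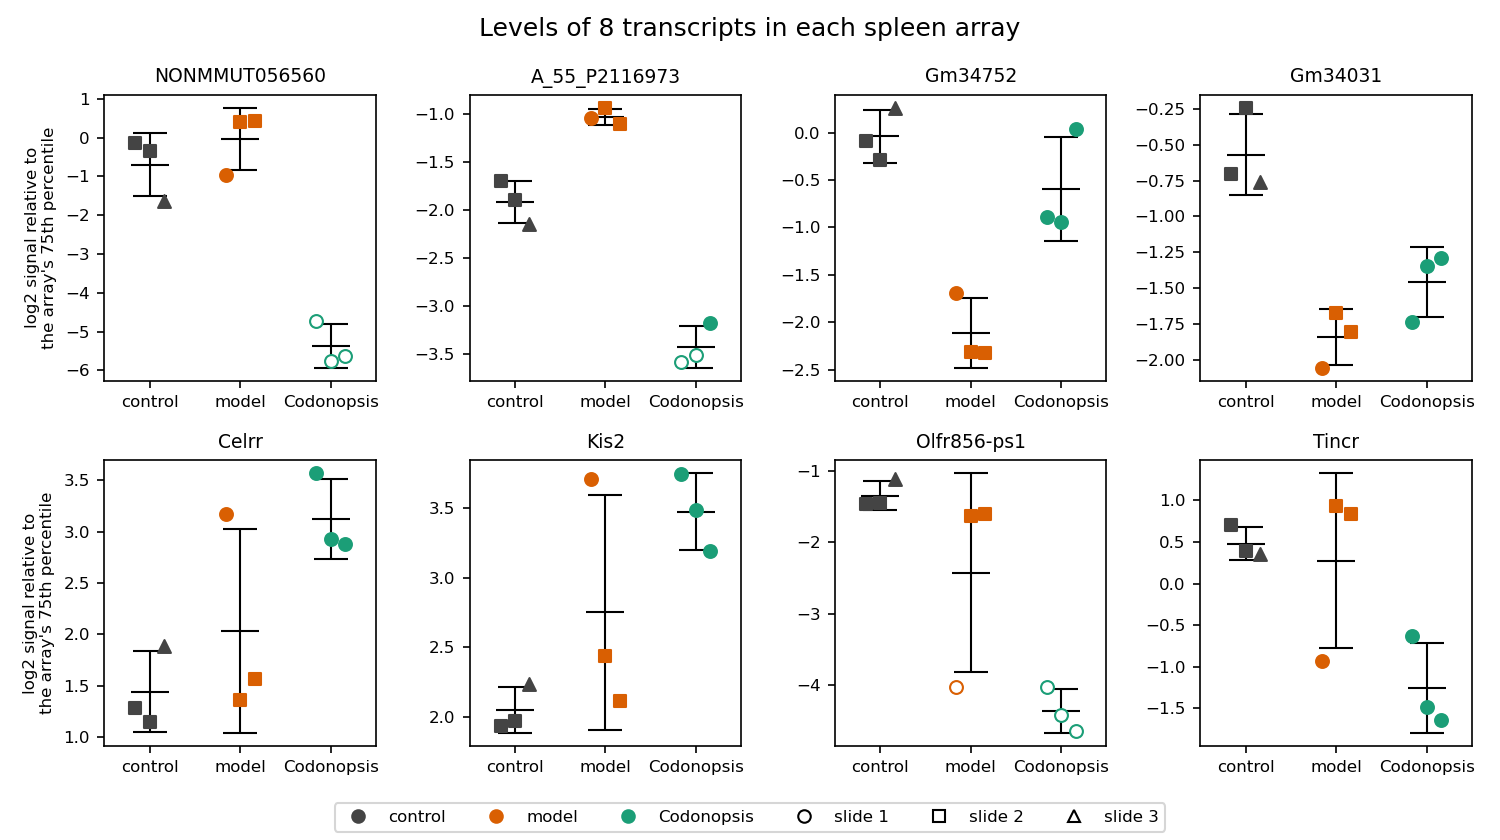
Log2 signal of 8 transcripts relative to the 75th percentile of each array, per array, with the group mean and SD (bars, n = 3); colours are groups, symbols are slides, and open symbols mark arrays on which the probe was not well above background. NONMMUT056560 and A_55_P2116973 separate Codonopsis from every model array, Gm34752 and Gm34031 separate model from control, and for Celrr, Kis2, Olfr856-ps1 and Tincr the model array on slide 1 lies with the Codonopsis arrays.

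Named genes did not pass in this comparison. Lower mean values with Codonopsis were measured for a noncoding transcript of Smim10l1 (difference -1.29, SE 0.32), Tmem181c-ps (-1.36, SE 0.36), AI463170 (-1.06, SE 0.30) and Tincr, a noncoding RNA known from keratinocyte differentiation (-1.53, SE 0.48), with adjusted p values of 0.215 to 0.216. A noncoding transcript of Scnn1b, the gene of the beta subunit of the epithelial sodium channel, was not well above background on any Codonopsis array. Its model mean lay 2.79-fold above the Codonopsis bound. That ratio was 3.83-fold for Olfr856-ps1, 2.63-fold for Zfp862-ps and 1.59-fold for the transcribed pseudogene Zxda. All 4 were well above background on only 2 of the 3 model arrays. The model mean thus holds a signal near background, and these ratios are not strict lower bounds. For Olfr856-ps1 and Zfp862-ps the arrays of both groups overlapped. Leaving aside genes with Gm or RIKEN clone names, Celrr was the only named gene with a mean at least 2-fold higher, 3.12 ± 0.39 with Codonopsis and 2.03 ± 0.99 in the model. On slide 1 alone the differences shrank to -0.69 for Smim10l1, -0.32 for Tincr and -0.05 for Celrr, and were -0.94 for Tmem181c-ps and -0.83 for AI463170. Olfr856-ps1, Scnn1b, Zfp862-ps and Zxda were not well above background on any array of slide 1, model replicate 1 included, so that slide holds no comparison of them. The noncoding transcript NONMMUT067196 was higher with Codonopsis by 1.44 (SE 0.23, adjusted p = 0.1998, limma) and by 1.57 on slide 1 alone.

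The lists gave no call in this comparison either (smallest camera adjusted p = 0.450). Host genes of small nucleolar RNAs had 4 of 6 higher with Codonopsis, with Snhg3 at a difference of 0.91 (SE 0.42) and Snhg9 at -1.45 (SE 0.56). The list linked to p53 or DNA damage, in which the place of Lincred2 is uncertain, had 2 of 5 higher. In it Norad, which guards genome stability, differed by 0.20 (SE 0.19). Lncpint differed by -0.79 (SE 0.24) without overlap between the arrays of both groups; it was the 1 member of that list past the threshold when adjusted over the list alone, and its difference was -0.70 on slide 1. Immune noncoding RNAs had 2 of 3 higher, with AW112010 at 0.41 (SE 0.45). Opposite-strand transcripts had 6 of 16 higher, and Speer4cos, well above background on 2 of the 3 Codonopsis arrays, differed by -1.78 (SE 0.67). Its Codonopsis replicate 2 alone read -5.70, not well above background, beside -2.85 and -3.70 on replicates 1 and 3. Transcribed pseudogenes had 23 of 57 higher, and noncoding transcripts of coding genes 7 of 20. On slide 1 the differences were 0.24 for Snhg3, -0.11 for Snhg9, 0.071 for Norad, 0.012 for AW112010 and -1.18 for Speer4cos. There the median of the host genes turned from 0.25 to -0.096, that of the p53 list from -0.074 to 0.071, that of the opposite-strand list from -0.33 to 0.025 and that of the transcripts of coding genes from -0.28 to 0.091.

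Transcripts 2-fold apart were more often lower than higher with Codonopsis, by a margin that depended on the scaling and that noncoding transcripts lost with slide as a block. At an unadjusted p under 0.05 and at least 2-fold, 1662 catalogue probes were lower and 420 higher than in the model, and 2444 noncoding transcripts were lower and 392 higher, 83.5% lower in all. The share was 70.7% with the percentile over all probes, which moved the median of all features from -0.08 to 0.06, and 68.8% with quantile normalization. Without the 2-fold limit the catalogue probes were 1438 higher and 2827 lower, but 2300 and 2233 with the percentile over all probes, 2111 and 2266 with quantile normalization, and 1510 and 1598 among probes detected on all arrays. The last filter drops probes that fell below background on a Codonopsis array, so its split cannot test the skew. Among RefSeq model noncoding transcripts the median difference was -0.34, against -0.01 among catalogue probes. With slide as a block these medians were 0.07 and -0.02. There 317 catalogue probes 2-fold apart were lower and 108 higher, but 232 noncoding transcripts were lower and 232 higher. Without the 2-fold limit, noncoding transcripts turned from 1177 higher and 3613 lower to 640 higher and 435 lower.

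The third comparison, Codonopsis against control, set treated mice beside untreated mice. No catalogue probe and no noncoding transcript passed (smallest adjusted p = 0.104, limma with Benjamini-Hochberg adjustment), while 5658 catalogue probes and 6490 noncoding transcripts lay at an unadjusted p under 0.05 with limma. Celrr averaged 3.12 ± 0.39 in Codonopsis and 1.44 ± 0.39 in control spleens, and Kis2, a noncoding gene known as a retroviral integration site, 3.47 ± 0.28 and 2.05 ± 0.16. The pseudogene Olfr856-ps1 was not well above background on any Codonopsis array and was at least 8.09-fold higher in control. The bound was 4.15-fold for Mtag2, 3.62-fold for the noncoding transcript of Scnn1b, 3.48-fold for Alkbh3os1, 3.30-fold for Zfp862-ps, 2.29-fold for Sox5os3, 2.03-fold for Zxda and 1.55-fold for the probe named ftx_mm_1. The curated probe with the symbol Ftx, tested as a separate feature, went the other way, with a difference of 0.24 (SE 0.31). Smim10l1 differed by -1.36 (SE 0.32), and the pseudogenes Olfr1077-ps1 and Selenok-ps1 by 1.44 (SE 0.55) and 1.43 (SE 0.65), the first well above background on only 1 of the 3 control arrays. H2-Q5 differed by 2.67 (SE 1.32), again with control replicate 3 alone at -6.37. NONMMUT056560 was at least 14.0-fold higher in control (adjusted p = 0.104 with limma).

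No array of slide 1 was a control array, so the slide block tied this comparison together only through the model arrays. With the block, the differences were 0.19 for Celrr, 0.09 for Kis2, -0.51 for Smim10l1, -0.53 for Selenok-ps1 and 1.80 for H2-Q5, and the adjusted p of NONMMUT056560 was 0.293 (limma). Olfr856-ps1, Mtag2, Scnn1b, Alkbh3os1, Zfp862-ps, Zxda and ftx_mm_1 were not well above background on any array of slide 1, nor Olfr1077-ps1 on any of slide 2, so the block could not compare them. At an unadjusted p under 0.05 the block left 747 catalogue probes and 771 noncoding transcripts, 3.29% and 3.98% of those tested, and slide as a random block 1269 and 1495. Leaving out model replicate 1, which is in neither group, changed the shared spread and gave 4441 catalogue probes and 5543 noncoding transcripts past the threshold, 2983 and 4572 of them lower with Codonopsis. A fit to the 2 groups alone gave 3174 and 4420.

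In the lists, host genes of small nucleolar RNAs had 4 of 6 higher with Codonopsis than in control, with Snhg16 at a difference of 0.996 (SE 0.29) and Snhg9 at -1.53 (SE 0.56). Immune noncoding RNAs had 2 of 3 higher, with AW112010 at 0.97 (SE 0.45). The list linked to p53 or DNA damage had 2 of 5 higher, with Norad at 0.39 (SE 0.19). Lincred2, whose place in it is uncertain, differed by -0.38 (SE 0.20). Opposite-strand transcripts had 4 of 16 higher, transcribed pseudogenes 21 of 57 and noncoding transcripts of coding genes 5 of 20. Adjusted over the list alone, Snhg16 passed in its list and Celrr in the immune list, in which its place is uncertain, as did 1 higher and 12 lower of the pseudogenes and 2 lower of the transcripts of coding genes; none passed over all features. The slide block gave differences of 0.67 for Snhg16, 0.026 for Snhg9, 0.49 for AW112010, 0.15 for Norad and -0.024 for Lincred2. The median of the host genes turned from 0.56 to -0.060, that of the opposite-strand list from -0.66 to 0.17, that of the pseudogenes from -0.22 to 0.012 and that of the transcripts of coding genes from -0.37 to 0.16. Camera called no list (smallest adjusted p = 0.186, and 0.488 with an estimated correlation).

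Read as Codonopsis given to the model, the design also asks whether the plant moved transcripts back toward control. The titles of the Codonopsis samples name the plant but no D-galactose or sodium nitrite. The labelled days differ as well, 42 for model and 30 for Codonopsis, and cannot be told apart from the treatment. No feature passed in both the model against control and the Codonopsis against model comparisons with opposite signs. By the looser rule of 2-fold at an unadjusted p under 0.05, 68 features had opposite signs and 12 the same sign in both, against 14.7 opposite for independent lists. Of the 68, 39 were higher in the model and lower with Codonopsis (10.2 for independent lists), and 29 were lower and then higher (4.56). Gm34752 was one that differed from model by 1.52 with Codonopsis (SE 0.32, adjusted p = 0.215 with limma), which left it at -0.56 (SE 0.32) against control. On slide 1 it read -0.89, -0.94 and 0.04 on the Codonopsis arrays and -1.69 on model replicate 1. Model replicates 2 and 3, on slide 2, read -2.32 and -2.33. The same model arrays enter both comparisons. In simulations of unchanged groups this alone gave opposite signs for 66.6% of features, beside 48.3% measured over all features. The counts for independent lists are therefore no fair benchmark, and the excess over them does not show a return toward control. Across all 42056 features the covariance of both differences was 0.0101, against -0.0900 in 100 simulations of unchanged groups that share the model arrays, a difference of 0.100. The correlation was 0.04 against -0.50 simulated. The simulation holds no slide effect, and a slide effect on model replicate 1 moves both differences, so this difference does not measure a shared effect. With slide as a block no array enters both differences, and their covariance was 0.0027.

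As a check of the labels, the sex given for each mouse was set beside sex-linked genes. Tsix was the only gene of that list with a named probe, and it was not well above background on any array. Another set of probes parted the arrays sharply. At a gap of 1.5 on the log2 scale, 84 probes were higher on all of Codonopsis replicate 3, model replicate 1 and control replicates 1, 2 and 3 than on any of Codonopsis replicates 1 and 2 and model replicates 2 and 3, and 7 probes were the reverse. Of the larger set, 67 were catalogue probes and 17 noncoding transcripts, and the files and tables pair none of the 91 with a gene name. No probe parted the 3 arrays labelled male from the 6 labelled female at that gap.

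**Figure D3:**
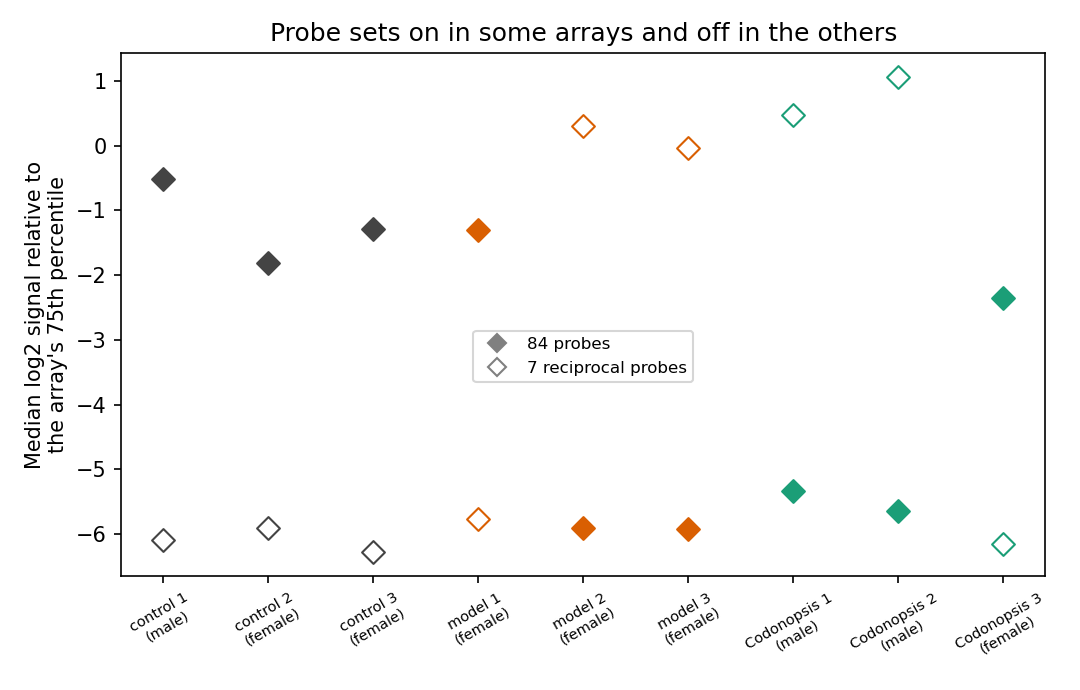
Median log2 signal, relative to the 75th percentile of each array, of the 84 probes (filled) and the 7 reciprocal probes (open) for each array, with the labelled sex in brackets. The filled set lies between -2.35 and -0.52 on 5 arrays and between -5.92 and -5.33 on the other 4, where the open set lies at -0.04 to 1.06; the arrays labelled male and female fall on both sides.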

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

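Counts of calls moved with several settings. Within-slide fits, slide as a random block and the splits by on and off probes were added after the data were seen, the 6 lists after the names on the array were read but before groups were compared, and the cause of the changes below was not tested unless stated. Model against control gave 0 calls of either kind in most settings, but 423 catalogue probes and 380 noncoding transcripts with array weights, 166 and 174 by the rule of 2-fold with an unadjusted p, and 74 and 29 within slide 2; the split by on and off probes as a covariate gave 1 noncoding transcript. Its features at an unadjusted p under 0.05 had no fixed direction: noncoding transcripts were 150 higher and 473 lower, but 1623 and 698 without the filter and 1577 and 838 within slide 2, and catalogue probes 320 and 211, but 486 and 842 with the slide block. Codonopsis against model gave 1 and 1. It gave 0 of both kinds under normexp, quantile normalization, the deposited matrix, the labelled sex and the slide block. Only probes detected on all 9 arrays also gave 0, but that filter leaves out both called features before any test. The percentile over all probes gave 0 catalogue probes. The fit to 2 groups gave 0 noncoding transcripts and 1 catalogue probe that was higher, so it shared no call with the reported fit. Array weights gave 10883 and 10449, and the 2-fold rule 2082 and 2836. In Codonopsis against control 0 became 2 catalogue probes under quantile normalization and under the deposited matrix, 3174 and 4420 in the fit to 2 groups, 9846 and 9804 with array weights, 2671 and 4010 by the 2-fold rule, 4173 and 5237 with the on and off split, and 1 noncoding transcript with the labelled sex. Array weights ranged from 0.147 for model replicate 1 to 5.47 for control replicate 1. Opposite features were 400 with array weights and 68 by the 2-fold rule. Slide as a random block (correlation 0.371), no filter, 1 feature per probe and trend with robust eBayes kept both calls of Codonopsis against model.

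Leaving out 1 array at a time gave 0 to 1 catalogue probes and 0 noncoding transcripts in model against control (1 without control replicate 1), 0 to 6009 and 0 to 6775 in Codonopsis against model, and 0 to 4441 and 0 to 5543 in Codonopsis against control; the highest values came without model replicate 1, and 2 catalogue probes without control replicate 1 and 4 without Codonopsis replicate 3 were the next. Opposite features were 0 to 1, the 1 without control replicate 1. Lists called stayed at 0, with an estimated correlation and with fry too, except 1 in model against control without control replicate 2. For the replicate numbers, same-numbered arrays had deviations that correlated between -0.51 and 0.38. These values show no pairing by number but cannot exclude one, since the slides enter the deviations. The replicate block gave 0 calls in Codonopsis against model and no other change of a count.

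Of 67 named values, 19 changed sign in at least 1 setting, none of them past the threshold in the reported fit. Slide with the on and off split gave 18 of the 27 changes of sign. In that fit Codonopsis against model is Codonopsis replicate 3 against model replicate 1, 1 array each. Model against control there is the slide 2 difference minus the difference of Codonopsis replicates 1 and 2 from replicate 3. Those values thus rest on few arrays and do not show how stable a sign is. With slide as a block Celrr in Codonopsis against model read -0.053 (the same within slide 1), and in Codonopsis against control Selenok-ps1 read -0.53, Snhg9 0.026 and Alkbh3os1 0.25, the last not well above background on any slide 1 array. With slide and the on and off split together, model against control read -0.037 for Snhg16, -0.25 for Lncpint, -0.13 for Celrr, -1.02 for AW112010 and 0.37 for Wt1os; Codonopsis against model read -0.30 for Celrr, 0.13 for Snhg9, -0.18 for Snhg3, -0.001375 for Norad and -0.99 for AW112010; Codonopsis against control read -0.62 for Kis2, -0.43 for Celrr, -0.052 for Olfr1077-ps1 (not well above background on slide 2), -0.16 for Selenok-ps1, -0.70 for Snhg16, 0.60 for Snhg9, -0.031 for Norad and -2.01 for AW112010. Wt1os in model against control read 0.094 with array weights and -1.17 to 0.041 leaving out 1 array, the latter without model replicate 1. AW112010 in Codonopsis against model read -0.12 with the labelled sex and -0.059 to 0.91 leaving out 1 array, the former without Codonopsis replicate 2. NONMMUT056560 and A_55_P2116973, well above background on 0 and 1 of the Codonopsis arrays, were lower in 25 settings each, past the threshold in 10 and 9 of them; those signals near background do not show how stable the size of either difference is. Gm34752 stayed between -2.29 and -1.19 in 26 settings. A covariate from Y-linked expression was not run, since no Y-linked gene of the sex check had a named probe, and the tests of the fixed lists could not be run.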

Other observations

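Except for 3 tests (those on weak signal over all features, and the skew of model replicate 1), the tests below were chosen after the result was seen. Model replicate 1 lay nearer to the Codonopsis arrays than to the other model arrays, at a mean distance of 0.49 against 0.86 (log2). Weak signal on slide 1 is argued against as the whole cause: in the brightest 25% of the features the ratio of both distances was 0.494, with all Codonopsis distances between 0.45 and 0.53 and the model distances between 0.99 and 1.01. A slide effect stays open, since without that array 4 pairs of one slide and different groups differed by 0.4996 on average and 2 pairs of one group on different slides by 0.56, with overlapping ranges. At a gap of 1.5 (log2), 367 probes set slide 2, with its model and control arrays, apart from all other arrays, control replicate 3 included. That goes with a slide effect, though model replicate 1 is itself among those other arrays. A wrong label stays open too: on slide 1, 2.71% of features lay at an unadjusted p under 0.05 between Codonopsis and model replicate 1, in a test with 1 array on one side that can exclude neither explanation. No biological explanation was tested, and another response of that mouse cannot be told apart from its slide.

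With Codonopsis 83.5% of the features that differed from model by the 2-fold rule were lower, and 68.8% to 82.3% under the other scalings and normexp. In the brightest 25% of the features 79.3% of 904 were lower, beside 91.5% of 2012 in the dimmest 25%, but the former share was 61.6% with the percentile over all probes. Weak signal alone is argued against for noncoding transcripts, with 73.4% to 87.8% of the bright ones lower over 5 scalings and background corrections. It stays open for catalogue probes, whose share depended on the scaling (53.9% to 75.1%). A slide effect may be part of it: model replicate 1 against the other model arrays, with no Codonopsis in either, had 72.8% of its 10672 2-fold differences lower. With slide as a block 61.8% of 889 features were lower (74.6% of the catalogue probes but 50% of the noncoding transcripts), and 54.4% in the brightest 25%, so slide and treatment cannot be told apart from these values.

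The 84 probes that were on in 5 arrays and off in 4, with 7 reciprocal probes, were the third most frequent division among the 126 ways to part the arrays 5 to 4; the division by slide 1 had 663 probes, that by slide 2 had 367, and the next after these had 5. The labelled sex is argued against, since 0 probes parted the labelled sexes at the same gap. The slide was not tested. The division was picked among those whose 4 arrays lay on more than 1 slide, so at least 1 slide with both sides followed from that choice. Here 2 slides held arrays of both sides, so the slide alone does not give this division. A candidate explanation is that the sex of some mice differs from the label, since the pattern has a reciprocal set of 7 probes; a code letter in the names of the deposited files, whose meaning the sources used here do not give, divides all 9 arrays the same way. It stays open because no named sex-linked gene was well above background. The off side held model replicates 2 and 3 and no control array. Of the 97 probes that were lower in the model within slide 2, 78 belonged to the larger set. The larger set was picked for a gap between these same arrays. Its probes are thus lower there by selection, and the overlap is no separate support.

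For each comparison the 6 arrays can be split in 10 ways, too few for a share under 0.05. In model against control the reported split gave 0 catalogue probes and 0 noncoding transcripts, and the highest of the other splits 1 and 1. In Codonopsis against model it gave 1 and 1, and the highest other 3304 and 4046. That split set Codonopsis replicate 1 with model replicates 2 and 3 against Codonopsis replicates 2 and 3 with model replicate 1, and points to a structure of the samples other than the groups. In Codonopsis against control the reported split and the highest other gave 0 of both kinds.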
